A study of Mus musculus with 10 samples.

How the data were processed

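Whole inner ears of mouse embryos at E16.5, 5 WT and 5 homozygous for nmf219 of Tbx1, were snap frozen, RNA was taken up in TRIzol, and libraries were made from 1 µg of total RNA with standard Illumina methods, per the labels' protocols. The aligner, the counting tool, its strand setting, the annotation and the genome build are not given in the sources used here. Groups came from the sample titles and genotype labels. Replicate numbers 1 to 5 occur in both genotypes, and nothing in the labels says that they pair animals. Numbers in the sample descriptions fall in 2 ranges that each hold both genotypes (2162 to 2169 and 2199 to 2208). Library numbers run from 7050 to 7054 in nmf219 and from 7058 to 7062 in WT, so an effect of library order and the genotype cannot be told apart.

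The deposited table lists 15472 genes, with 1 normalized signal per library, headed as counts and CPM per the file headers. The deposited columns sum to 990643 to 1009220, so they are not plain CPM: each value is a whole number of reads times 1 step per library, and the authors' scaling equals TMM factors up to 1 constant (computed here; lowest factor 0.991, highest 1.01). Whole reads came out in 100% of values in each library within a tolerance of 0.01 read, and 1 read is worth 0.0239 to 0.0317. The table also gives the authors' log2 fold change of mutant against control, a signed fold change, and the authors' p-value and FDR, per the file headers; the means in the table are those of the 10 library columns. Nearly all listed genes have a value of at least 1 in 2 or more libraries (15469), so genes below about that level had been removed before deposit. The table holds positions for 15336 genes; 15309 identifiers were found in GENCODE M21 (GRCm38), and of these 79.8% had the same start and end and 90.5% at least 1 same end. Coordinates are printed as the table gives them. The table names no symbol for 136 genes. A further 22 symbols had been turned into calendar dates, and their names were restored from the identifiers.

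Since the table holds normalized values, the main test was limma (3.58.1, trend) on log2(value + 1) with genotype as the only term, over all 15472 genes, with Benjamini-Hochberg adjustment and a threshold of 0.05. The plan made before the data were examined gave edgeR's quasi-likelihood test for counts and this test for tables without counts. Gene lists, 30 of them fixed before the data were examined, were tested with camera on log2(value + 1), in place of the planned voom values, with a preset inter-gene correlation of 0.01 and with an estimated correlation. The lists cover marginal cells, melanocytes, fibrocytes, hair cells, supporting cells, tectorial membrane and otoconia, endolymphatic duct, canals, otic patterning, retinoic acid, Tbx1 targets, potassium recycling, hearing loss, ganglion neurons, glia, cartilage, bone, muscle, erythroid cells, macrophages, endothelium, brain, epidermis, airway epithelium, cell cycle, immediate early and heat shock genes, hypoxia, interferon, mitochondrial genes and ribosomal proteins. A list of 10 choroid plexus genes was added later. Comparisons of single values used two-sided exact permutation tests of 5 against 5, which cannot go below p = 0.00794, or Fisher's exact test.

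The rule for named genes, set before the data were examined, took Tbx1, up to 10 genes per direction with the largest log2 fold change among those past the test with a mean value of at least 1 and every library on its genotype's side of the other genotype's mean, leaving out Xist, Tsix, Y-linked genes and unnamed models, and up to 4 called members of each list or, in lists without any, the most abundant member. Results for some genes are not reported here; they remain in the counts.

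Precision was set by spread between libraries more than by depth: 3 reads correspond to values of 0.0716 to 0.0952. On simulated counts with the means, depth and spread of this comparison over 15472 genes, the test recovered 27 of 50 genes changed 1.25-fold, 38 of 50 at 1.5-fold, 48 of 50 at 2-fold and 48 of 50 at 3-fold, with 7 false calls among 15272 unchanged genes. Genes were simulated without shared variation between libraries, such as that of muscle RNA. The simulation changed 200 genes and gave 168 calls, against 13 in the data, so its adjusted threshold let through larger unadjusted p-values. These shares therefore overstate what the test could find here. Esrrb, for example, was 2.59-fold lower in nmf219 and did not pass (limma adjusted p = 0.114).

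Alternatives were other scalings, a stricter filter, pseudocounts of 0.1 and 0.5, limma-voom, DESeq2 (1.42.0), a replicate block, a block on the description number, Xist as a covariate, 1 surrogate variable (sva 3.50.0) and leaving out each library. Added after the data were seen were edgeR (4.0.16) quasi-likelihood on the recovered reads, which called 11 genes, all among the 13, covariates for the muscle list and for Hbb-y, the subset without the 3 WT libraries with Y-linked RNA, and exact permutation tests of list means. R 4.3.3 was used, with matplotlib 3.10.9 for the plots.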

Results

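RNA was sequenced from whole mouse inner ears at embryonic day E16.5, from 5 wild-type (WT, +/+) and 5 homozygous nmf219 samples on the C57BL/6 background. The nmf219 allele lies in Tbx1, which encodes a T-box transcription factor that acts in the developing otic vesicle and the tissue around it. The listed genes held 35293445 to 40942278 reads per library in nmf219 and 31244799 to 41875972 in WT (exact permutation test of log2 reads, two-sided, p = 0.357, 5 against 5). Within each genotype no library was a second sequencing run of another, since all 20 pairs differed by 7.93 to 61.1 times the chi-square per degree of freedom that sampling noise gives; this does not show that the libraries came from separate animals. The labels name 5 samples per genotype and do not say whether each came from a separate animal or litter, so p-values measure the spread between these samples. RNA of the Y-linked genes Ddx3y, Eif2s3y and Kdm5d was at a value of at least 1 in 3 of 5 WT and 0 of 5 nmf219 libraries (two-sided Fisher's exact test, p = 0.167). In the other libraries the highest of these values was 0.114, for Kdm5d in nmf219 replicate 1. Embryo sex was thus not balanced between the genotypes.

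The comparison of nmf219 with WT asks which transcripts of the inner ear differ at this age when Tbx1 carries the nmf219 allele. The mutant ears held far less RNA of Kcne1, the auxiliary subunit of the potassium channel that secretes potassium into endolymph, and less RNA of the protocadherin Pcdh20, of the T-box factor Tbx3 and of the pigment cell protein Pmel. Kcne1 was 13.9-fold lower, Pcdh20 3.11-fold lower, Pmel 1.56-fold lower and Tbx3 1.48-fold lower in the mean of 5 nmf219 than of 5 WT libraries, and in each case all nmf219 libraries lay below all WT libraries. Only Col6a4, a collagen VI chain, and the cadherin Cdh7 were higher among the genes past the test. RNA of Tbx1 itself did not differ detectably.

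Tbx1 (ENSMUSG00000009097, chromosome 16, 18581713 to 18586969 in the coordinates of the deposited table) was at a normalized value of 24.3 ± 4.08 (SD, n = 5) in WT and 25.2 ± 2.02 (SD, n = 5) in nmf219. The WT libraries, replicates 1 to 5, were at 29.3, 20.7, 21.6, 28.1 and 21.7. The nmf219 libraries were at 25.3, 23.0, 26.1, 23.7 and 28.1. The log2 fold change was 0.06 (SE 0.10), with limma adjusted p = 0.872 and exact permutation p = 0.595 (two-sided). An allele of this kind need not change the level of its own RNA, so this value does not check the labels.

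Over the 15472 genes of the table, 13 passed limma's test at a Benjamini-Hochberg adjusted p under 0.05, 2 higher and 11 lower in nmf219, and 1100 had an unadjusted p under 0.05. Fold changes below are nmf219 against WT on the scale of log2(value + 1), which understates the change of genes at low values; folds between means are on the scale of the values. Kcne1 (ENSMUSG00000039639, chromosome 16, 92346001 to 92359468) was at 4.72 ± 2.54 (SD, n = 5) in WT and 0.340 ± 0.0573 (SD, n = 5) in nmf219, a log2 fold change of -1.98 (SE 0.24, limma adjusted p = 0.00838). Pcdh20 (ENSMUSG00000050505, chromosome 14, 88464743 to 88471396) was at 40.3 ± 2.38 in WT and 12.9 ± 0.872 in nmf219, with a log2 fold change of -1.57 (SE 0.06) and the smallest limma adjusted p of the table, 1.06e-07. Tbx3 (ENSMUSG00000018604, chromosome 5, 119670669 to 119684724) went from 34.0 ± 0.637 to 23.0 ± 0.552, a log2 fold change of -0.55 (SE 0.03, limma adjusted p = 1.45e-05). Its antisense neighbour Tbx3os1, whose gene model overlaps the start of Tbx3 on the other strand, was 2.83-fold lower. The sources do not state whether reads were counted by strand, so reads of this pair in the overlap cannot be assigned to either gene.

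Among the other lower genes, Atp2c2, a calcium and manganese pump of the secretory pathway, was 3.24-fold lower at 1.94 ± 0.350 in nmf219 against 6.28 ± 1.58 in WT. The amine receptor gene Taar5 was 2.82-fold lower and the ion pump gene Atp13a4 2.55-fold lower, both from values near 2 in WT. Neither passed edgeR's test on the recovered reads (edgeR adjusted p = 0.0525 for Taar5 and 0.0600 for Atp13a4). Of the 16 alternatives that did not just leave out 1 library, Taar5 lost the call in 7 and Atp13a4 in 9. Nr4a3, an orphan nuclear receptor that takes part in semicircular canal growth, was 1.67-fold lower. Rnf149, a ubiquitin ligase gene, was at 48.8 ± 3.16 in WT and 39.0 ± 1.28 in nmf219 and was the 11th lower gene; it fell outside the rule for named genes and was chosen after its values were seen. Col6a4 rose 2.99-fold, from 0.905 ± 0.180 to 2.71 ± 0.583, with limma adjusted p = 0.00838, and Cdh7 rose 2.40-fold, from 0.909 ± 0.224 to 2.19 ± 0.354, with limma adjusted p = 0.0274. All 13 genes had separate ranges in the 2 genotypes; 181 genes of the table (1.17%) did, where chance gives 0.794%. Numbers in the sample descriptions fall in 2 ranges, and with these as a block 13 genes passed, 11 of them among the 13. Kcne1 was at a log2 fold change of -2.26 in numbers 2162 to 2169 (2 WT and 3 nmf219) and -1.83 in 2199 to 2208 (3 WT and 2 nmf219).

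**Figure D1:**
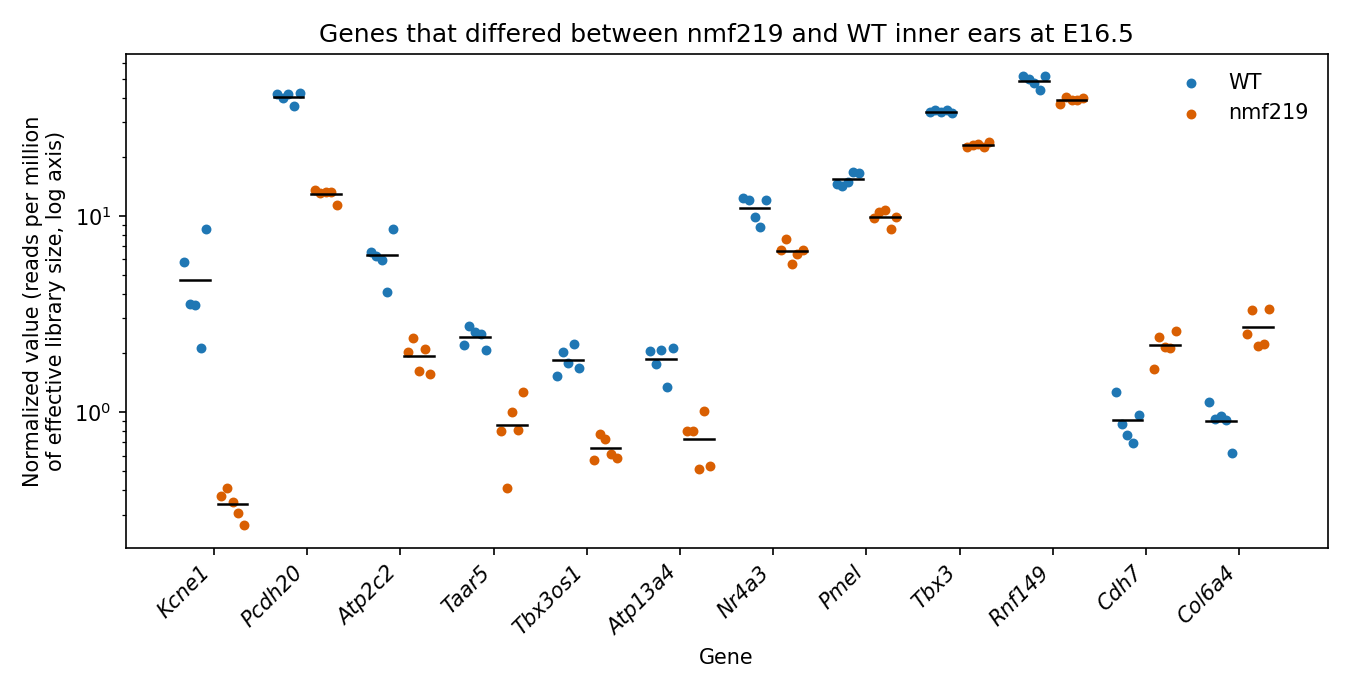
Normalized value of 12 of the 13 genes past the test in each library, on a log axis, with 5 WT (blue) and 5 nmf219 (orange) points per gene and a bar at each mean. In all 12 genes the points of the genotypes do not overlap, and Kcne1 shows the widest gap, 4.72 against 0.340 in the means.

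The calls rested on the model in part, in both directions. DESeq2 called 63 genes (16 higher and 47 lower), all 13 included. Among them were 4 Y-linked genes and several members of the lists below that limma did not call over all genes, such as Esrrb, Abcg1, Dct, Gpnmb, Mitf, Pax2, Otx2, Zic1 and Slc32a1. With Hbb-y as a covariate, an alternative added after the data were seen, 33 genes passed limma's test (5 higher and 28 lower), all 13 included. With Xist RNA as a covariate for embryo sex, 2 genes passed (Pcdh20 and Tbx3), and with the mean of the skeletal muscle list as a covariate, an alternative added after the data were seen, 3 passed (Pcdh20, Tbx3 and Atp2c2); Kcne1 was then at -2.07 and -2.08 with limma adjusted p = 0.0919 and 0.108. Kcne1 also lost the call under limma-voom on the recovered reads (-3.57, limma-voom adjusted p = 0.0501) and with a replicate block (-1.98, limma adjusted p = 0.119). Against the 2 WT libraries without Y-linked RNA, an added alternative, 10 genes passed, 6 of them among the 13, and Kcne1 was at -2.06 with limma adjusted p = 0.00114. Both genes that were higher in the main test, Col6a4 and Cdh7, lost the call there, as did Pmel, Tbx3os1, Taar5 and Atp13a4. Cdh7, Taar5, Nr4a3, Atp13a4 and Rnf149 lost the call in 5 to 9 of the 10 refits without 1 library, while Kcne1, Pcdh20, Tbx3, Tbx3os1, Atp2c2, Pmel and Col6a4 kept it in all 10.

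Several genes of the stria vascularis, the tissue that secretes endolymph, were lower in the mutant ears, while others did not differ detectably. In the list of marginal cells, 9 of 11 measured genes were lower and the list passed the competitive test (camera with a preset correlation, adjusted p = 4.61e-06; adjusted p = 0.323 with an estimated correlation). Adjusted over the list alone, 6 members fell and 1 rose; over all genes only Kcne1 passed limma's test. Esrrb, a nuclear receptor needed by marginal cells, went from 29.9 to 11.5, a log2 fold change of -1.24 (SE 0.23). The chloride channel subunit gene Bsnd fell by 0.80 on the log2 scale, at low values that overlapped, 0.657 to 2.61 in WT and 0 to 0.966 in nmf219. The lipid transporter gene Abcg1 fell by 0.31. Heyl, a target of Notch signalling, rose by 0.15. Kcnq1 (-0.03), Lmx1a (-0.03) and Slc12a2 (0.00) did not differ detectably. The median log2 fold change of the list was -0.16, against a mean of -0.45. The mean of the list was 4.52 ± 0.269 (SD, n = 5) in WT and 4.07 ± 0.0830 in nmf219, with no overlap between the genotypes (exact permutation p = 0.00794, the smallest that 5 against 5 can give; adjusted over 30 lists 0.119).

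Most pigment cell genes were lower too. In the list of melanocytes and intermediate cells, 9 of 12 genes were lower (camera adjusted p = 2.24e-07; adjusted p = 0.162 with an estimated correlation), and 6 fell when adjusted over the list alone. Beside Pmel these were Dct (log2 fold change -0.52), Tyrp1 (-0.51), Gpnmb (-0.43), Slc45a2 (-0.35) and Mitf (-0.31), which encode enzymes, membrane proteins and the master transcription factor of pigment cells. Over all genes, Pmel alone passed limma's test. The 3 members that were not lower were Kcnj10 (0.29), Ednrb (0.21) and Kit (0.01). The mean of the list was 3.44 ± 0.0745 in WT and 3.20 ± 0.0884 in nmf219 (SD, n = 5 each; exact permutation p = 0.0159, adjusted 0.119).

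In the list of otic patterning transcription factors, not all of which act in the otic epithelium alone, 17 of 21 genes were lower (camera adjusted p = 1.64e-06, and adjusted p = 0.323 with an estimated correlation). Adjusted over the list alone, 6 fell: Tbx3, Otx2 (log2 fold change -0.74), Pax2 (-0.54), Pax3 (-0.35), Dlx3 (-0.34) and Msx2 (-0.29). Pax3 was at low values, 1.23 in WT and 0.758 in nmf219. Over all genes only Tbx3 passed limma's test. The mean of the list was 4.74 ± 0.0835 in WT and 4.58 ± 0.0627 in nmf219 (SD, n = 5 each; exact permutation p = 0.0159, adjusted 0.119), and the genotypes overlapped, since nmf219 replicate 5 was at 4.69 and the WT libraries ranged from 4.62 to 4.85. The list of brain tissue markers, transcripts that a dissection of the ear can carry, was lower as well, with 7 of 8 genes lower and Zic1 (-0.22), Dlx2 (-0.31) and Slc32a1 (-0.50) past the test adjusted over the list alone. It was the 1 list that also passed with an estimated correlation (camera adjusted p = 1.20e-05; adjusted p = 0.0367 with an estimated correlation), and none of its members passed limma's test over all genes. Zic1 and Dlx2 encode transcription factors also used outside the brain, and Slc32a1 encodes the transporter that loads inhibitory transmitter into vesicles. The members Gad2 (0.05) and Slc17a6 (-0.03) did not differ detectably. The estimated correlation between members was -0.01, against 0.89 in the skeletal muscle list, so the brain list genes did not vary together between libraries. Whether carried brain tissue lowered this list was not tested.

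Skeletal muscle transcripts were higher in the nmf219 libraries, and they were also the most uneven group among libraries. All 17 muscle genes were higher in the mean of nmf219, by a median log2 fold change of 1.59 (camera adjusted p = 5.03e-12; adjusted p = 0.323 with an estimated correlation), and 13 rose when adjusted over the list alone, among them Ckm (2.33), Myh8 (2.06) and Acta1 (2.01). None passed over all genes. Myh3, embryonic myosin, was at 235 ± 263 (SD, n = 5) in WT and 487 ± 241 in nmf219 (limma adjusted p = 0.680). The list mean ranged from 2.76 to 6.06 in WT and from 4.88 to 6.59 in nmf219, so that the genotypes overlapped (exact permutation p = 0.0556, adjusted 0.268). Without WT replicate 3 the WT range was 2.76 to 4.40 and they did not overlap.

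Further lists passed the competitive test with small shifts, given below as the mean log2 fold change, then the camera adjusted p with the preset correlation. Hair cell genes were higher in 22 of 23 cases (0.14, 0.000318; adjusted p = 0.568 with an estimated correlation) and endothelial genes in 12 of 12 (0.12, 1.64e-06; adjusted p = 0.323 with an estimated correlation). Macrophage genes were higher in 13 of 14 cases (0.18, 8.37e-05; adjusted p = 0.469 with an estimated correlation), Schwann cell and glial genes in 11 of 13 (0.10, 0.00675; adjusted p = 0.372 with an estimated correlation) and epidermal genes in 8 of 8 (0.37, 0.00892; adjusted p = 0.469 with an estimated correlation). Immediate early and heat shock genes were higher in 11 of 13 cases (0.11, 0.0215; adjusted p = 0.323 with an estimated correlation). Cell cycle genes were lower in 16 of 16 cases (-0.14, 0.000162; adjusted p = 0.580 with an estimated correlation) and cartilage genes in 13 of 16 (-0.13, 0.000723; adjusted p = 0.568 with an estimated correlation). No member of these 8 lists passed limma's test, either over all genes or adjusted over the list alone. Single libraries moved these shifts. Without WT replicate 4 the mean log2 fold changes were 0.0728 for hair cells, 0.0846 for macrophages, -0.0568 for cartilage, -0.0706 for the cell cycle and 0.133 for epidermis, and epidermis no longer passed (camera adjusted p = 0.0540). Without WT replicate 5 they were 0.585 for epidermis and -0.216 for the cell cycle. Glia did not pass without WT replicate 3 (0.0842, camera adjusted p = 0.0548), nor did immediate early and heat shock genes without WT replicate 1 (0.108, 0.0823) or nmf219 replicate 1 (0.0760, 0.0749). With the mean of the muscle list as a covariate, cartilage turned to 0.0204 and did not pass (camera adjusted p = 0.603), and macrophages (0.0573), epidermis (-0.0259) and immediate early and heat shock genes (0.0480) did not pass either. With Xist as a covariate hair cells (0.0730), glia (0.0451) and cartilage (-0.0547) did not pass, and against the 2 WT libraries without Y-linked RNA hair cells (0.0715) and glia (0.0406) did not. Myo6 of the hair cells, at 133 ± 18.8 in WT and 141 ± 12.7 in nmf219, and Col2a1 of cartilage, at 12423 ± 1655 and 11948 ± 1608, differed by less than the spread between libraries. Cdh5, Mrc1, Pmp22, Krt15, Mki67, Hsph1 and Foxp1, the most abundant members of the endothelial, macrophage, glial, epidermal, cell cycle, heat shock and brain lists, did not pass over all genes, with limma adjusted p-values of 0.680 or more.

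**Figure D2:**
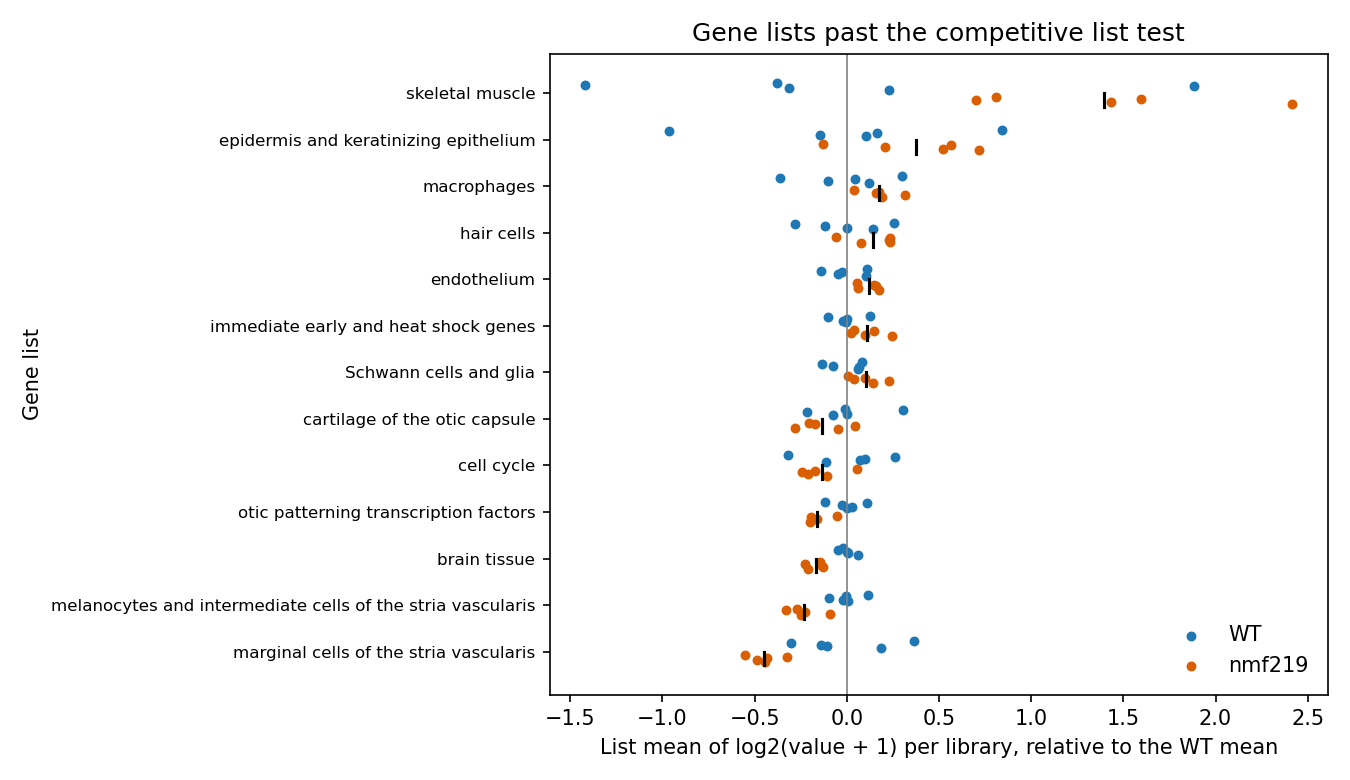
Mean of log2(value + 1) over the genes of each of the 13 lists past the competitive test, per library and relative to the WT mean, with WT in blue, nmf219 in orange and a bar at the nmf219 mean. The genotypes are apart in the marginal cell and brain lists, and the muscle list spans the widest range, from 2.76 to 6.59 in list mean.

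In all, 13 of 30 lists passed with the preset correlation, 7 higher and 6 lower. Splits of the libraries other than by genotype gave a median of 10 lists with this test, so passing it does not by itself tie a list to genotype. All 13 had the same sign within both ranges of description numbers. They were picked by their shifts in these same libraries, so this is no separate support. With an estimated correlation 1 list passed, and the exact permutation test of the list means, added after the data were seen, called 0 lists after adjustment, with 5 at an unadjusted p under 0.05. Libraries also differed in the embryonic globin Hbb-y, which was at 11.4, 15.8, 20.5, 44.4 and 3.10 in WT replicates 1 to 5 and at 6.15, 4.28, 3.66, 4.15 and 33.0 in nmf219 replicates 1 to 5 (exact permutation p = 0.238). With Hbb-y as a covariate, an added alternative, the hair cell, macrophage, epidermal, glial, cell cycle and immediate early lists no longer passed. The other 7 of the 13 did, as did potassium recycling, lower.

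**Figure D3:**
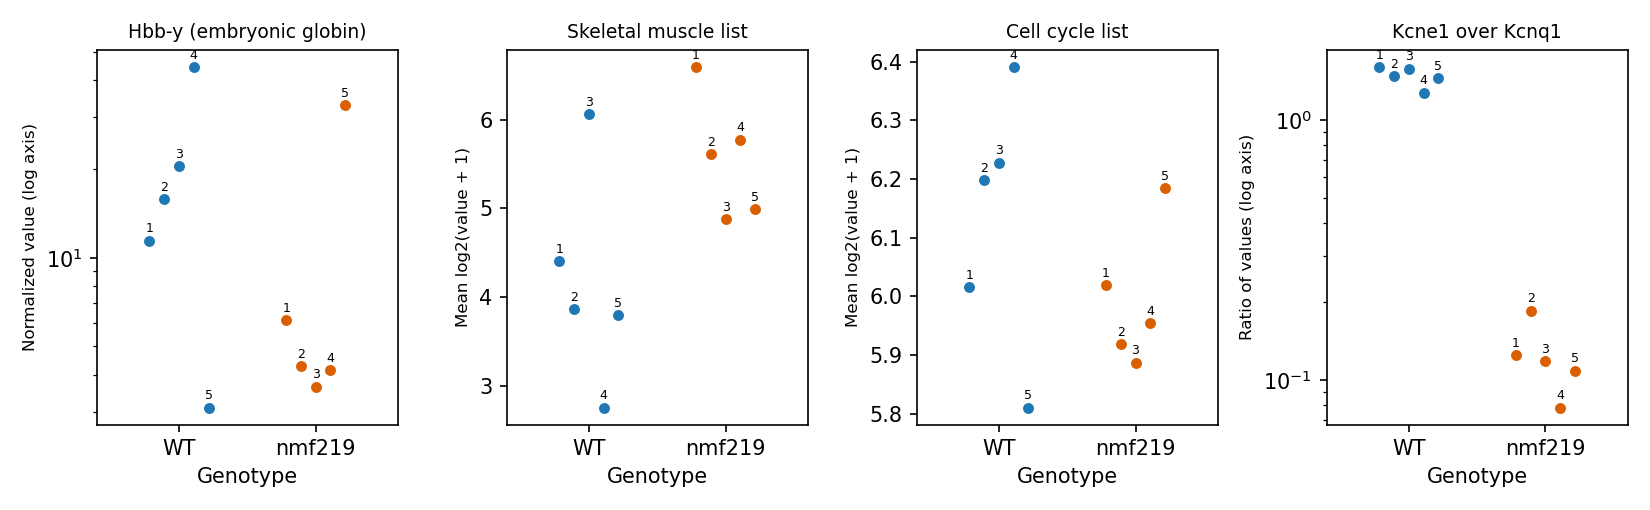
Values per library for the embryonic globin Hbb-y, the means of the skeletal muscle and cell cycle lists, and the ratio of Kcne1 to Kcnq1, with replicate numbers beside the points. WT replicate 4 and nmf219 replicate 5 have the highest Hbb-y of their genotypes, 44.4 and 33.0, and the ratio lies between 1.27 and 1.59 in WT and between 0.0784 and 0.185 in nmf219.

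The remaining 17 lists did not pass. Among the lists of the inner ear, periotic fibrocytes (camera adjusted p = 0.161), supporting cells (0.277), tectorial membrane and otoconia (0.105), the endolymphatic duct and sac (0.143) and semicircular canal development (0.192) held their most abundant or called members Otor, Fgfr3, Col11a2, Car2 and Nr4a3. Single members passed when adjusted over the list alone: Nox3, an oxidase needed for otoconia, rose from 2.86 to 6.22 (log2 fold change 0.97, SE 0.26), and Nr4a3 fell in the canal list. Otor, Fgfr3, Col11a2 and Car2 had limma adjusted p-values from 0.680 to 0.852; Fgfr3 was at 177 ± 42.8 in WT and 140 ± 12.7 in nmf219.

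Among pathways, retinoic acid metabolism (camera adjusted p = 0.871), genes reported downstream of Tbx1 in other organs (0.964), potassium recycling (0.946) and hereditary hearing loss genes (0.629) did not pass. The retinol transporter gene Stra6 fell by 0.19 on the log2 scale when adjusted over its list alone, and Kcne1, Esrrb, Mitf and Edn3 fell among the 52 hearing loss genes. Rxra and Wnt5a, the most abundant members of the retinoic acid and Tbx1 lists, were at log2 fold changes of 0.00 and -0.01. For potassium recycling and hearing loss genes the competitive test pointed higher while the means were -0.07 and -0.01, and for spiral and vestibular ganglion neurons it pointed lower while the mean was 0.00.

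Ganglion neurons (camera adjusted p = 0.946; Nefm 189 in WT and 192 in nmf219), bone (0.193; Runx2 62.1 and 66.9), erythroid cells (0.161; Hba-a1 2181 and 2609) and airway epithelium (0.342; Ccdc39 at a log2 fold change of -0.01) did not pass. In the bone list Spp1 rose by 0.48 and Dlx3 fell by 0.34 on the log2 scale when adjusted over the list alone. Hypoxia and glycolysis genes (0.962; Ldha 398 and 384), interferon response (0.0622; Ifi27 23.7 and 26.8), mitochondrially encoded genes (0.629; mt-Co1 8557 and 8740) and cytoplasmic ribosomal proteins (0.161; Rplp0 1343 and 1339) did not pass either.

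The authors' deposited table carries its own comparison of the same libraries. At an FDR under 0.05 the authors' deposited table called 505 genes, 395 higher and 110 lower, against 13 with limma here, and 12 of the 13 were among them. Rnf149 was the exception, with an FDR of 0.0679 in the authors' deposited table. All 505 genes had the same sign here, and 56 of them had separate ranges in the genotypes. Of the 17 muscle genes, 15 were called higher in the authors' deposited table, and 168 of its 395 higher genes (42.5%) followed the muscle list mean within the genotypes at a Pearson correlation above 0.8, against 2.0% of all genes. An exact test of the recovered reads that gave all genes 1 common dispersion of 0.0129 called 505 genes, 505 of them those of the authors' deposited table.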

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

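The tests of embryo sex, choroid plexus RNA, an equal loss of cells, muscle amounts, embryo maturity and genotype, and the splits for the gene count, were chosen after the values they rest on were seen; the splits for the list count were not.

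Single libraries stood apart from the other 4 of their genotype in 9 of 134 groups examined, where chance gives about 1 in 20. In nmf219 replicate 5, Pcdh20 was at 11.4 against 13.1 to 13.6 in the others, Runx2 at 54.5 against 67.8 to 72.5 and Hsph1 at 109 against 82.3 to 87.6. In the same library the mean of the otic patterning list was 4.69 against 4.54 to 4.58, and that of the bone list 3.19 against 3.60 to 3.76. In WT replicate 4, Fgfr3 was at 252 against 148 to 172 and Rplp0 at 1449 against 1303 to 1328. Myh3 was at 693 in WT replicate 3 against 48.4 to 210, and Hba-a1 at 4297 in WT replicate 5 against 1128 to 1920.

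The first pattern is the lower Kcne1 and other marginal cell genes. Against the 2 WT libraries without Y-linked RNA, Kcne1 was still at -2.06 (limma adjusted p = 0.00114), and with the choroid plexus list as a covariate at -1.87 (SE 0.25, limma adjusted p = 0.0350), which argues against embryo sex or choroid plexus RNA as the whole cause of its fall. With Xist as a covariate the call ended at -2.07 (SE 0.32, limma adjusted p = 0.0919), against -1.98 (SE 0.24) without it: the fold stayed and the SE widened. The call also ended with limma-voom (-3.57, adjusted p = 0.0501), the replicate block (-1.98, 0.119) and the muscle covariate (-2.08, 0.108). The 11 list members moved apart, from -1.98 to 0.15, with an SD of 0.651 between their log2 fold changes against a median SE of 0.0894. Relative to Kcnq1, a ratio chosen after values were seen, Kcne1 was at 1.27 to 1.59 in WT, although Kcnq1 itself ran from 1.67 to 5.96. In nmf219 the ratio was 0.0784 to 0.185, with Kcnq1 at 2.23 to 3.89. This argues against an equal loss of cells that hold both RNAs as the whole cause of the fall in Kcne1. For the list as a whole, an equal loss would give unequal folds too if other tissue supplies part of the RNA. There, a loss of cells cannot be told apart from a lower level per cell in whole ears. Library order, which follows the genotype, stays open as well.

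The second pattern is the higher skeletal muscle RNA. The muscle list mean spanned 3.30 on the log2 scale within WT and 1.71 within nmf219, both more than the 1.39 between the genotype means. Varying amounts of muscle carried along at dissection would give this, but so would any other source of spread between libraries. The comparison of spans with the difference also rests on single libraries. Without WT replicate 3, the 1 WT library inside the nmf219 range, the WT libraries spanned 1.65 and the means differed by 1.86, more than either span. Without nmf219 replicate 1 the nmf219 libraries spanned 0.896 and the means differed by 1.14. Dissection and genotype (exact permutation p = 0.0556) therefore cannot be told apart.

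The third pattern is the set of small shifts in 6 lists, cell cycle and cartilage lower and hair cells, macrophages, endothelium and epidermis higher. Embryos of different maturity at 1 nominal age may account for part of it, since the means of 5 of the 6 lists followed log2 Hbb-y, a globin that is switched off during development, within the genotypes. Over 10 libraries, as deviations from the genotype means, Pearson's r was 0.94 for cell cycle (Spearman's rho 0.90; permutation p of 0.0003 for both, adjusted over 6 lists 0.0015 and 0.0018) and -0.93 for hair cells (rho -0.87; p = 0.0005 and 0.0010, adjusted 0.0015 and 0.0030). Macrophages, endothelium and epidermis were at r = -0.82, -0.75 and -0.83 (permutation adjusted p = 0.0151 each; rho -0.62, -0.71 and -0.56, adjusted p = 0.101, 0.0614 and 0.141), and for cartilage no relation was detected (r = 0.14, permutation p = 0.723; rho -0.07, p = 0.873). Without the 2 libraries with the most extreme deviations in Hbb-y, r was 0.96 for cell cycle, -0.89 for hair cells, -0.71 for macrophages, -0.56 for endothelium and -0.64 for epidermis, so that 4 of the 6 lists, without endothelium, followed at an r beyond 0.6. With Hbb-y as a covariate 2 of the 6 calls held, cartilage and endothelium, although cartilage turned to 0.0204, not past the test, with the muscle list as a covariate, while the mean log2 fold change moved from 0.14 to 0.02 for hair cells, from -0.14 to -0.01 for cell cycle and from 0.12 to 0.0693 for endothelium, so genotype cannot be told apart from maturity for the other 4, with Hbb-y uneven between the genotypes. Without WT replicate 4 the shifts were 0.0728 for hair cells, 0.0846 for macrophages, -0.0568 for cartilage, -0.0706 for cell cycle and 0.133 for epidermis, which no longer passed, and without WT replicate 5 they were 0.585 for epidermis and -0.216 for cell cycle.

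Splits of the 10 libraries into 5 and 5 other than by genotype bear on both counts. Of 100 splits drawn, the real one included, 4 gave 13 or more genes, narrowly under 5 in 100. The 3 others gave 83, 230 and 978 genes, far more than the real one. Not every possible split was drawn, and the test was chosen after values were seen. The count of 13 alone therefore does not firmly exclude chance or a structure of the samples. The split with 978 sets WT replicates 1 to 4 and nmf219 replicate 5 (Hbb-y 11.4 to 44.4) against the rest (3.10 to 6.15), which points to such a structure. The former side holds 4 of 5 WT libraries and 4 of the 5 libraries with description numbers 2199 to 2208, so it follows both in part, beside Hbb-y. With a block on the description number 13 genes passed, 11 of them among the 13. For lists, 21 of the 100 splits gave 13 or more, up to 17, and the median of the splits other than the real one was 10. Chance therefore cannot be excluded for the number of lists.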

How the results depend on the processing

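The edgeR test, the covariates for muscle and Hbb-y, the subset without Y-linked RNA and the permutation test of list means were chosen after the data were seen. The count of 13 genes stayed within 1.5 times under the other scalings, the filter, the pseudocounts, limma-voom, edgeR, the block on description number, 1 surrogate variable and the subset, but not with the same genes: limma-voom lost Kcne1. DESeq2 called 63 genes (16 higher, 47 lower), the 13 included, and Hbb-y as a covariate 33 (5 and 28), the 13 included; Xist left 2 and the muscle list 3. The cause was not tested. The replicate block left 2 genes. Deviations of same-numbered libraries correlated at -0.48 to 0.14, and 0 of 5 WT libraries correlated best with its own number. Paired animals need not correlate in this measure, so whether the replicate numbers pair animals stays open. Leaving out 1 library gave 7 to 18 genes: 7 without WT replicate 2, nmf219 replicate 3 or nmf219 replicate 4, and 8 without nmf219 replicate 1.

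Tbx3 and Pcdh20 kept their calls in all 16 other alternatives and 10 refits without 1 library; Kcne1, Atp2c2, Pmel, Tbx3os1 and Col6a4 kept theirs in the 10 refits. Kcne1 lost its call with limma-voom (-3.57, adjusted p = 0.0501), the replicate block, Xist and the muscle list. Cdh7, Taar5, Nr4a3, Atp13a4 and Rnf149 lost theirs in 7, 5, 9, 9 and 9 of these, with limma adjusted p up to 0.161; no called gene changed sign. Tbx1 stayed at 0.01 to 0.18 on the log2 scale, adjusted p 0.636 to 1.00.

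With Hbb-y as a covariate 8 lists passed, 7 of the 13 and potassium recycling, which turned to a lower call, -0.17; 1 passed with an estimated correlation and 0 by permutation of list means (5 at an unadjusted p under 0.05). Of the 13, 8 passed with the muscle covariate, which removes the muscle list by design, 10 with Xist and 11 in the subset, beside 3, 1 and 2 further lists. Leaving out 1 library gave 12 to 16. The ribosomal list, uncalled at -0.01, was called higher with Xist (0.0387), the muscle covariate (0.0283), the subset (0.0339) or without WT replicate 4 (0.0165; the refits without 1 library ran from -0.0342 to 0.0165). Cartilage turned to 0.0204 with the muscle covariate. The cause of these turns was not tested. A further 129 uncalled values changed sign and stayed uncalled. No run without a filter was possible, since the table was filtered before deposit, and unrounded counts did not apply. At this depth a gene with 3 reads is at 0.0716 to 0.0952.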

Other observations

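The tests of chromosome position and of pigment cells with marginal cells, the choroid plexus list, the ratios to Kcnq1 and the genes named with the Hbb-y covariate were all chosen after values were seen.

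With Hbb-y RNA as a covariate, 33 genes passed limma's test over all genes, 28 of them lower. They include 4 of 11 marginal cell genes (1 without the covariate), 2 of 12 pigment cell genes (1) and 2 of 21 otic patterning genes (1). Esrrb was at a log2 fold change of -1.54 (SE 0.11, limma adjusted p = 0.000107), against -1.24 and adjusted p = 0.114 without the covariate. Abcg1 (-0.37) and the pigment cell enzyme gene Dct (-0.58) passed too, as did Pax2 (-0.41), the Wnt inhibitor gene Sfrp5 (-0.74) and the retinoic acid synthesis gene Aldh1a2 (-0.57). Among the genes that were higher were Nos2 (0.54) and Dkk2 (0.25), beside Col6a4 and Cdh7. DESeq2 called 25 of the 33 without any covariate, among them Esrrb (-1.37, DESeq2 adjusted p = 0.000577), Abcg1, Dct, Pax2, Sfrp5, Nos2 and Dkk2, and limma called Esrrb (-1.36, adjusted p = 0.0254) and Nos2 against the 2 WT libraries without Y-linked RNA. DESeq2 did not call the other 8, Aldh1a2 among them.

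Relative to Kcnq1, the channel subunit that Kcne1 joins, Kcne1 was at 1.27 to 1.59 in WT and 0.0784 to 0.185 in nmf219, and Esrrb at 7.57 to 11.9 in WT and 3.20 to 5.48 in nmf219 (exact permutation p = 0.00794 for each).

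Choroid plexus genes, which a dissection near the brain can carry, differed among WT libraries. Ttr was at 208, 37.3, 41.0, 2.12 and 4.06 in WT replicates 1 to 5 and between 2.67 and 15.3 in nmf219. The mean of 8 measured choroid plexus genes was 2.0 to 3.76 in WT and 2.23 to 2.74 in nmf219 (exact permutation p = 0.302).

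Of the 13 called genes, 2 lie on chromosome 16, where Tbx1 lies, among 473 genes tested there: Atp13a4, 10808884 bases from Tbx1, and Kcne1, 73759032 bases from it. A candidate explanation, less so for the far more distant Kcne1, is a passenger difference linked to the mutated gene. The two-sided Fisher's exact test (p = 0.0582) neither shows nor excludes it, since it counted the whole chromosome and not the region near Tbx1.

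Pigment cells and marginal cells of the stria lie side by side, so their lists could vary together through 1 shared source. Within the genotypes their means were related at Pearson's r = 0.36 (permutation p = 0.321; Spearman's rho 0.37, p = 0.278; 10 libraries, and r = 0.01 without the 2 farthest in the pigment cell mean), which leaves this open.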
